A study of Homo sapiens with 9 samples.

How the data were processed

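Poly-A selected, stranded RNA sequencing libraries of HEK293T cells were compared between control, SIN3A and SIN3B siRNA, with 3 libraries in each of 3 groups, 36 h after transfection with 10 nM siRNA. The groups were taken from the sample titles and source names, because the treatment text of every sample ends with the control siRNA. The count table holds read counts per Ensembl gene that the authors, per their deposited processing notes, made by trimming with Trimmomatic 0.36, aligning to GRCh38 with HISAT2 2.1.0 and counting with HTSeq (no version given). The FPKM table was deposited by the authors with the same genes and libraries, and the count to FPKM ratio was constant between libraries, up to the library factor, to 0.0028% in 4456 genes with high counts in every library. The length behind these FPKM values had a Spearman rho of 0.00239 with exon length in GENCODE 29 across 12258 genes, so FPKM values were compared only within a gene. The authors' notes name DESeq2 1.20.0 for their own testing, and no table of it was used. The strand setting of the counting is not given, so values of genes that overlap on opposite strands, such as SYT2 and PPP1R12B, are uncertain.

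Counts were analysed as deposited in edgeR 4.0.16 (R 4.3.3) with TMM scaling, the filterByExpr filter at its defaults (minimum count 10, minimum total count 15) and the quasi-likelihood F-test, in a single fit of all 9 libraries with 6 residual degrees of freedom. Of 58734 genes, 31909 had no count and 16686 were tested, 13467 of them protein-coding. The 3 comparisons were each knockdown against control and the SIN3A against the SIN3B knockdown. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and are two-sided. Levels are TMM-scaled CPM with the SD over 3 libraries, and log2 fold changes carry the standard error of the fit. A change of direction between knockdowns was read from the direct comparison.

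Before the data were examined, 38 gene lists were fixed, and 37 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with its p-values adjusted over the 37 lists. The list of metallothioneins had 4 tested members and was not run. Camera with a correlation estimated per list and the rotation test fry were run beside it. The lists hold 796 genes in all, 9 of them in more than 1 list. Genes were named by a rule fixed at the same time: SIN3A, SIN3B and 10 known partners or cell-cycle genes, the 8 largest rises and 8 largest falls per knockdown (6 each way in the direct comparison) among called genes above 1 log2 CPM whose libraries did not overlap, the 3 members with the lowest adjusted p of each called list, and 5 genes per kind of overlap. The rule also covers lists with 3 called members that failed the camera test; some of these are given as counts and the rest are left out. Some genes that the rule names were left out of the text because they are withheld for evaluation.

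Overlap of the knockdowns was compared with the product of the list sizes over the genes tested, and with 20 simulations in which 2 unchanged groups were set against the same 3 controls. Annotated 3′ UTRs of 10336 genes above 2 log2 CPM were scanned for 7-base sequences whose presence goes with a lower log2 fold change. On simulated data, planted 2-fold changes were recovered in 68.2% (SIN3A) and 69.8% (SIN3B) of cases and planted 1.5-fold changes in 52% and 53%, with 5.65% and 5.54% of calls false. These simulations, and those with shared controls, gave each gene a single spread for all groups. They cannot show the share of false calls where the SIN3A knockdown libraries lie further apart than the others. A planted 7-base shift was recovered in 20 of 20 scans.

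Alternatives were other scaling factors, filters, DESeq2 1.42.0, limma on log2 FPKM with pseudocounts of 1 and 0.1, a fold threshold of 1.2, fits of 6 libraries, the replicate number as a block, length offsets and leaving out each library. Chosen after seeing the data were counts divided by 4, offsets for GC content and exon length, the lists under upper-quartile factors, and leaving out genes with a seed-type site. Figures were drawn with matplotlib 3.10.9.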

Results

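Gene expression was measured by poly-A selected RNA sequencing in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. The cells were transfected for 36 h with 10 nM of control siRNA, siRNA against SIN3A or siRNA against SIN3B, with 3 libraries in each group. SIN3A and SIN3B are paralogous scaffold proteins on which a histone deacetylase complex with HDAC1 and HDAC2 is assembled, and the series set out to compare what each of them does in these cells. The deposited counts summed to 22542798 to 27084884 per library over 58734 genes. In each library 98% or more of the nonzero counts were multiples of 4, so a unit of 4 counts was taken as the smallest step. The floor of 3 such units, or 12 deposited counts per library, lay at 0.443 to 0.532 CPM (counts scaled to a common library size) and covers counting error only.

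The libraries separated by siRNA. The first principal component held 25.1% of the variance and set the 3 SIN3A knockdown libraries apart from the rest, and the second held 19.6% and separated control from SIN3B knockdown libraries. Replicates of the control and SIN3B knockdown groups differed by a chi-square per degree of freedom of 1.42 to 1.98 on counts divided by 4. The 3 SIN3A knockdown libraries lay further apart, at 3.53 to 7.37, and the third component separated replicate 1 of that group from the other 2. No pair of libraries agreed within sampling noise, so each counted as 1 replicate. The labels do not say whether replicates came from separate transfections, so the p-values measure the spread between these libraries, which may be technical. The main fit gave each gene a single spread for all groups, although the SIN3A knockdown libraries lay further apart. Fits of only the 6 libraries compared called 3151 genes (SIN3A against control) and 5358 (SIN3B against control), in place of 3836 and 3939. The like call numbers of the main fit thus depend on that choice.

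Each siRNA lowered its own target and left the paralog where it was within the spread of the libraries. SIN3A (ENSG00000169375, chromosome 15, 75369379 to 75455842 on the minus strand of GRCh38) was at 146 ± 4.0 CPM (SD, n = 3) in control libraries and 47.3 ± 2.5 CPM in the SIN3A knockdown, which left 32.5% of the control level. Its log2 fold change was -1.62 ± 0.07 (SE, edgeR quasi-likelihood adjusted p = 2.2e-11). SIN3B (ENSG00000127511, chromosome 19, 16829400 to 16880353 on the plus strand) went from 96.2 ± 4.7 CPM in control libraries to 55.1 ± 3.6 CPM in the SIN3B knockdown, so 57.3% remained, and its log2 fold change was -0.80 ± 0.09 (edgeR adjusted p = 2.3e-06). SIN3B was at 96.9 ± 11 CPM in the SIN3A knockdown, with a log2 fold change of 0.01 ± 0.09 (edgeR adjusted p = 0.95). SIN3A was at 145 ± 4.8 CPM in the SIN3B knockdown, with a log2 fold change of -0.01 ± 0.07 (edgeR adjusted p = 0.97). The SIN3B siRNA thus removed a smaller share of its target than the SIN3A siRNA did, and the counts cover whole genes, not single exons or isoforms.

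**Figure D1:**
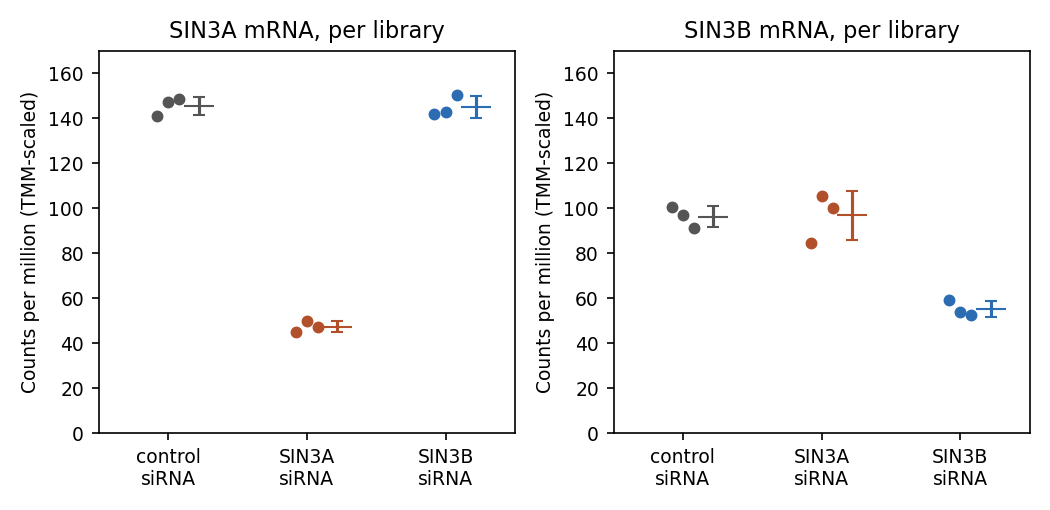
SIN3A (left) and SIN3B (right) mRNA in TMM-scaled CPM in each library, by siRNA, where dots are libraries and the bar beside them is the mean with its SD (n = 3). SIN3A lay between 44.9 and 49.9 CPM in the SIN3A knockdown and at 141 CPM or more elsewhere, and SIN3B between 52.3 and 59.2 CPM in the SIN3B knockdown and at 84.6 CPM or more elsewhere.

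The first comparison asked which transcripts changed when SIN3A was reduced. In the SIN3A knockdown, many neuronal genes fell, while many p53 target genes, lysosomal genes and inhibitors of cyclin-dependent kinases rose. Of 7 lists called, 2 (neuronal genes and p53 targets) were also called with an estimated correlation. Of 16686 genes tested, 2029 rose and 1807 fell (edgeR quasi-likelihood test, adjusted over all genes). Of those that changed at least 2-fold, 86 rose and 387 fell. The largest rise among genes above 1 log2 CPM was that of EIF5A2, a paralog of the translation factor eIF5A, from 3.92 ± 1.1 to 15.8 ± 2.4 CPM (log2 fold change 2.01 ± 0.20). ITIH5, a protease inhibitor heavy chain (1.87 ± 0.37), SPEF1, a microtubule-binding protein of cilia and flagella (1.65 ± 0.41), and CDKN1C, the cyclin-dependent kinase inhibitor p57 (1.59 ± 0.28), came next. FAM214B (1.51 ± 0.15), MIR22HG, the host transcript of microRNA 22 (1.49 ± 0.18), VMAC (1.43 ± 0.28) and the skeletal muscle sodium channel SCN4A (1.43 ± 0.38) completed the 8 largest rises.

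The 8 largest falls above 1 log2 CPM were in genes of low expression, each at 3.7 to 4.7 CPM in control libraries and under 1 CPM after SIN3A knockdown. FNDC5, the precursor of irisin, had the lowest log2 fold change of these at -2.58 ± 0.32. SYT2, a calcium sensor of synaptic vesicle release, was at -2.46 ± 0.33, FAM198A at -2.40 ± 0.32, FNDC1 at -2.35 ± 0.34 and ACSL6, a long-chain acyl-CoA synthetase, at -2.33 ± 0.35. NRXN2, a presynaptic adhesion protein (-2.27 ± 0.40), SLC24A4, a sodium, potassium and calcium exchanger (-2.11 ± 0.35), and ELFN2 (-2.09 ± 0.37) followed. ACSL6 and ELFN2 held 1 copy each of a 7-base sequence, GGTCTAA or AGGTCTA, in the 3′ UTR. All 16 genes were called with edgeR adjusted p of at most 0.0095. Their 3 knockdown libraries all lay on one side of the 3 control libraries, which the naming rule required and which adds no evidence. Without control replicate 1, SCN4A was no longer called, at 1.227 (edgeR adjusted p = 0.0591).

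Among the 28 neuronal genes measured, 14 fell and 0 rose over all genes tested (14 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.985. The camera adjusted p was 2.74e-11, and the adjusted p was 0.0106 with an estimated correlation. SYP, a synaptic vesicle membrane protein, fell from 44.5 ± 4.9 to 14.2 ± 1.2 CPM (-1.65 ± 0.12), NEFM, the medium neurofilament subunit, by 0.79 ± 0.07 on the log2 scale, and the microtubule regulator STMN3 by 0.97 ± 0.10. REST, a repressor of neuronal genes that recruits SIN3, rose by 0.68 ± 0.10. Of the 27 p53 targets, 17 rose and 1 fell (17 and 2 adjusted over the list alone), with a median of 0.43, a camera adjusted p of 1.6e-08 and an adjusted p of 0.0106 with an estimated correlation. CDKN1A, the kinase inhibitor p21, rose from 75.3 ± 2.9 to 137 ± 14 CPM (0.87 ± 0.09), the antiproliferative gene BTG2 by 0.82 ± 0.09 and the proapoptotic BAX by 0.64 ± 0.08. The member that fell was PMAIP1, which encodes the proapoptotic protein NOXA, at -1.26 ± 0.16.

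Of 10 CDK inhibitors and pocket proteins, 6 rose and 1 fell (the same counts adjusted over the list alone), with a camera adjusted p of 0.0107 and an adjusted p of 0.18 with an estimated correlation. CDKN1A and CDKN1B, the kinase inhibitor p27 (0.81 ± 0.11), rose, and RB1, the retinoblastoma protein, fell by 1.06 ± 0.13. The 3′ UTR of RB1 held 1 copy of GGTCTAA or AGGTCTA. Of 27 lysosome and autophagy genes, 13 rose and 2 fell (15 and 2 adjusted over the list alone), among them the protease CTSA (0.62 ± 0.08) and ATP6V0D1, a subunit of the lysosomal proton pump (0.58 ± 0.08). The camera adjusted p was 4.45e-06, and the adjusted p was 0.18 with an estimated correlation.

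Other parts of the SIN3 complex changed too. Of 22 SIN3 complex subunits, 10 rose and 2 fell (12 and 3 adjusted over the list alone), with a camera adjusted p of 0.00223 and an adjusted p of 0.18 with an estimated correlation. HDAC1 rose by 0.48 ± 0.06, HDAC2 by 0.23 ± 0.07 and the DNA-binding subunit ARID4A by 0.87 ± 0.11, whereas the histone chaperone RBBP4, whose 3′ UTR held 1 of the 7-base copies, fell by 0.61 ± 0.06. SAP30 (0.23 ± 0.13, edgeR adjusted p = 0.22) and SINHCAF (0.18 ± 0.09, edgeR adjusted p = 0.16) did not pass the test. Among DNA-binding factors that recruit SIN3, MXD1, a MAX partner, rose by 0.49 ± 0.14, and FOXK1 was at -0.09 ± 0.14 (edgeR adjusted p = 0.72). MYC fell by 0.22 ± 0.07. These small changes depended on the processing. With offsets for GC content and exon length HDAC2 was at 0.053 (edgeR adjusted p = 0.67) and MYC at -0.145 (edgeR adjusted p = 0.0857), and with upper-quartile factors HDAC2 was at 0.161 (edgeR adjusted p = 0.13). With 1 library fewer these calls were lost while the values moved less: HDAC2 was at 0.240, 0.230 and 0.224 (edgeR adjusted p of 0.065, 0.0626 and 0.0855) without control replicates 1, 2 and 3, and MXD1 at 0.434, 0.426 and 0.371 (0.0772, 0.0856 and 0.0771) without control replicates 1 and 2 and SIN3A knockdown replicate 3. MYC was at -0.227, -0.161 and -0.198 (0.0643, 0.176 and 0.0562) without control replicates 1 and 3 and SIN3A knockdown replicate 3. SAP30 passed without SIN3A knockdown replicate 3 (edgeR adjusted p = 0.0488) and with the offsets (0.0486).

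Of 36 G1/S genes driven by E2F factors, 12 rose and 2 fell (the same counts adjusted over the list alone), with a camera adjusted p of 0.0107 and an adjusted p of 0.429 with an estimated correlation. Under upper-quartile scaling the camera adjusted p of this list was 0.0696. CCNE1, cyclin E1 (chromosome 19), doubled from 49.6 ± 3.4 to 100 ± 4.1 CPM (1.01 ± 0.08), TK1, thymidine kinase, rose by 0.40 ± 0.09 and GINS1, a replication fork protein with 1 of the 7-base copies, fell by 0.60 ± 0.09. Of 34 HOX genes, which pattern the body axis, 1 rose and 12 fell (the same counts adjusted over the list alone), with a camera adjusted p of 0.00549 and an adjusted p of 0.18 with an estimated correlation. With offsets for GC content and exon length the camera adjusted p was 0.144. HOXA7 rose by 0.73 ± 0.11, and HOXB9 (-0.37 ± 0.07) and HOXC4 (-0.50 ± 0.09) fell. The 4 lists of markers of other cell types (epithelial, squamous, fibroblast and haematopoietic) had camera adjusted p of 0.129, 0.796, 0.869 and 0.956 in this comparison.

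The split of calls in the SIN3A knockdown depended on the scaling: with upper-quartile factors 1352 genes rose and 2313 fell, in place of 2029 and 1807. Of the 1347 fallen genes whose 3′ UTR was searched, 16.6% held GGTCTAA or AGGTCTA, against 6.9% of the other genes, and without all genes that held either, 1913 rose and 1535 fell.

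The second comparison asked the same of SIN3B. In the SIN3B knockdown, most tested genes of the G2 and M phases of the cell cycle rose, while many immediate early, glycolytic, hypoxia-responsive, fatty acid synthesis and neuronal genes fell. These list calls were made by camera at its preset correlation. With an estimated correlation 0 lists were called, and 17 with fry, which does not set a list against the other genes. Neuronal genes and p53 targets lost the call at estimated correlations of 0.00352 and 0.00254, under the preset 0.01. The size of the correlation thus does not account for these losses. Of 16686 genes tested, 2001 rose and 1938 fell (edgeR quasi-likelihood test, adjusted over all genes), and with upper-quartile factors 1693 rose and 2286 fell. Of those that changed at least 2-fold, 94 rose and 233 fell. HOXA7, a homeobox transcription factor, had the largest rise among genes above 1 log2 CPM, from 15.2 ± 1.2 to 44.8 ± 3.9 CPM (log2 fold change 1.56 ± 0.11, edgeR adjusted p = 6.4e-09). EIF5A2 rose by 1.56 ± 0.20, KPNA5, an importin alpha of nuclear import, by 1.50 ± 0.17, ENPP5 by 1.50 ± 0.21 and PI4K2B, a phosphatidylinositol 4-kinase, by 1.50 ± 0.22. C2orf69 (1.35 ± 0.24), COMMD10 (1.34 ± 0.20) and ANKRD12 (1.31 ± 0.18) completed the 8.

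Among genes above 1 log2 CPM, the lowest log2 fold change was that of NOG, the bone morphogenetic protein antagonist noggin, at -2.19 ± 0.24, from 8.90 ± 1.9 to 1.94 ± 0.31 CPM. CA12, a carbonic anhydrase (-1.80 ± 0.25), SLC16A9, a monocarboxylate transporter family member (-1.76 ± 0.18), and PARD6A, a cell polarity protein (-1.75 ± 0.37), followed. SLC2A4, the insulin-responsive glucose transporter (-1.67 ± 0.26), the Wnt antagonist APCDD1 (-1.67 ± 0.28) and STUM (-1.67 ± 0.21) came next. A 7-base sequence, ACAGCCT or CAGCCTT, stood in the 3′ UTR of 5 of these 7 genes (CA12, SLC16A9, SLC2A4, APCDD1 and STUM).

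Of 37 G2/M genes, 28 rose and 1 fell (31 and 2 adjusted over the list alone), with a median log2 fold change of 0.436. The camera adjusted p was 6.99e-18, and the adjusted p was 0.079 with an estimated correlation. TTK, a kinase of the spindle checkpoint, rose from 45.0 ± 5.4 to 103 ± 15 CPM (1.19 ± 0.12), and ECT2, an exchange factor needed for cytokinesis, by 0.92 ± 0.09. The member that fell was PLK1, a kinase of mitotic entry and spindle assembly (chromosome 16), from 234 ± 6.1 to 89.4 ± 7.1 CPM (-1.39 ± 0.07, edgeR adjusted p = 4.9e-10). Its 3′ UTR held 1 copy of the 7-base sequence, as did that of CDKN1A.

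Of 36 G1/S genes driven by E2F factors, 4 rose, 7 fell and 25 were not called (5 and 11 adjusted over the list alone), with a camera adjusted p of 0.00926 and an adjusted p of 0.502 with an estimated correlation. With offsets for GC content and exon length the camera adjusted p was 0.0806. RRM2, a ribonucleotide reductase subunit, fell from 148 ± 2.6 to 66.6 ± 1.1 CPM (-1.15 ± 0.07), the transcription factor E2F1 by 0.97 ± 0.07 and TK1 by 0.86 ± 0.09. CDKN1B rose by 0.98 ± 0.11, and 7 of 27 p53 targets rose and 1 fell (the same counts adjusted over the list alone), with a camera adjusted p of 0.014 and an adjusted p of 0.167 with an estimated correlation. CCNG1, cyclin G1, rose by 0.78 ± 0.09 and the stress-responsive SESN2 by 0.43 ± 0.07, and the p53 target that fell was CDKN1A, from 75.3 ± 2.9 to 47.5 ± 3.9 CPM (-0.66 ± 0.09).

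Of 18 immediate early genes, the first responders to growth factors, 11 fell and 0 rose (the same counts adjusted over the list alone), with a median of -0.502, a camera adjusted p of 8.66e-06 and an adjusted p of 0.265 with an estimated correlation. MYC fell from 181 ± 11 to 116 ± 3.8 CPM (-0.64 ± 0.07), JUNB by 0.75 ± 0.12 and SRF, which drives many of them and held 2 copies of the 7-base sequence, by 0.50 ± 0.08. Of 28 neuronal genes, 9 fell and 0 rose (the same counts adjusted over the list alone), with a camera adjusted p of 8.65e-05 and an adjusted p of 0.079 with an estimated correlation. The intermediate filament genes INA (-1.20 ± 0.10), NEFM (-0.83 ± 0.07) and NEFL (-0.79 ± 0.09) led them, with 1 copy of the sequence each in INA and NEFM. REST rose by 0.44 ± 0.10, a call that was lost with offsets for GC content and exon length (0.235, edgeR adjusted p = 0.0852).

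Of 19 glycolysis genes, 11 fell and 0 rose (12 and 0 adjusted over the list alone), with a camera adjusted p of 7.6e-05 and an adjusted p of 0.502 with an estimated correlation. SLC2A1, the main glucose transporter of proliferating cells, fell from 142 ± 18 to 57.2 ± 4.1 CPM (-1.31 ± 0.10), the enolase ENO2 by 0.62 ± 0.10 and GAPDH by 0.42 ± 0.08. Of 16 hypoxia targets, 8 fell and 0 rose (10 and 2 adjusted over the list alone), among them PFKFB3 (-0.71 ± 0.09) and PFKFB4 (-0.66 ± 0.11, with 2 copies of the 7-base sequence), regulators of glycolytic flux, and PDK1, a brake on mitochondrial pyruvate use (-0.49 ± 0.09). The camera adjusted p was 0.00366, and the adjusted p was 0.588 with an estimated correlation. Of 11 fatty acid synthesis genes, 8 fell and 1 rose (10 and 1 adjusted over the list alone), with a camera adjusted p of 0.000262 and an adjusted p of 0.154 with an estimated correlation. The desaturase FADS1 (-0.64 ± 0.07, with 2 copies), the acetyl-CoA synthetase ACSS2 (-0.66 ± 0.11) and fatty acid synthase FASN (-0.51 ± 0.09) fell. The 7-base sequence stood in the 3′ UTR of 5 of the 11 members, against 25.9% of the genes searched. The camera call held in the 12 alternative settings run. Without genes with a seed-type site anywhere in the mRNA, too few members remained to test the list. Other metabolic lists were not called: nuclear-encoded oxidative phosphorylation had 5 rises and 1 fall among 37 (2 and 1 adjusted over the list alone, camera adjusted p = 0.751), and cholesterol synthesis and uptake 5 and 4 among 23 (the same counts adjusted over the list alone, camera adjusted p = 0.865).

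Of 22 SIN3 complex subunits, 7 rose and 3 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.311). HDAC1 rose by 0.38 ± 0.06, and HDAC2 (0.11 ± 0.07), SAP30 (0.26 ± 0.13), SINHCAF (-0.20 ± 0.09), FOXK1 (-0.05 ± 0.14) and MXD1 (-0.07 ± 0.14) did not pass the test, with edgeR adjusted p of 0.12 to 0.85. With offsets for GC content and exon length SINHCAF (-0.362, edgeR adjusted p = 0.00294) and SAP30 (0.375, edgeR adjusted p = 0.0274) passed, and HDAC2 passed in the fit of 6 libraries (0.113, edgeR adjusted p = 0.028). Of the 1602 fallen genes whose 3′ UTR was searched, 39.6% held ACAGCCT or CAGCCTT, against 23.4% of the other genes, and without all genes that held either, 1628 rose and 1211 fell. The 4 lists of markers of other cell types had camera adjusted p of 0.315 (epithelial), 0.945 (squamous), 0.311 (fibroblast) and 0.945 (haematopoietic).

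**Figure D2:**
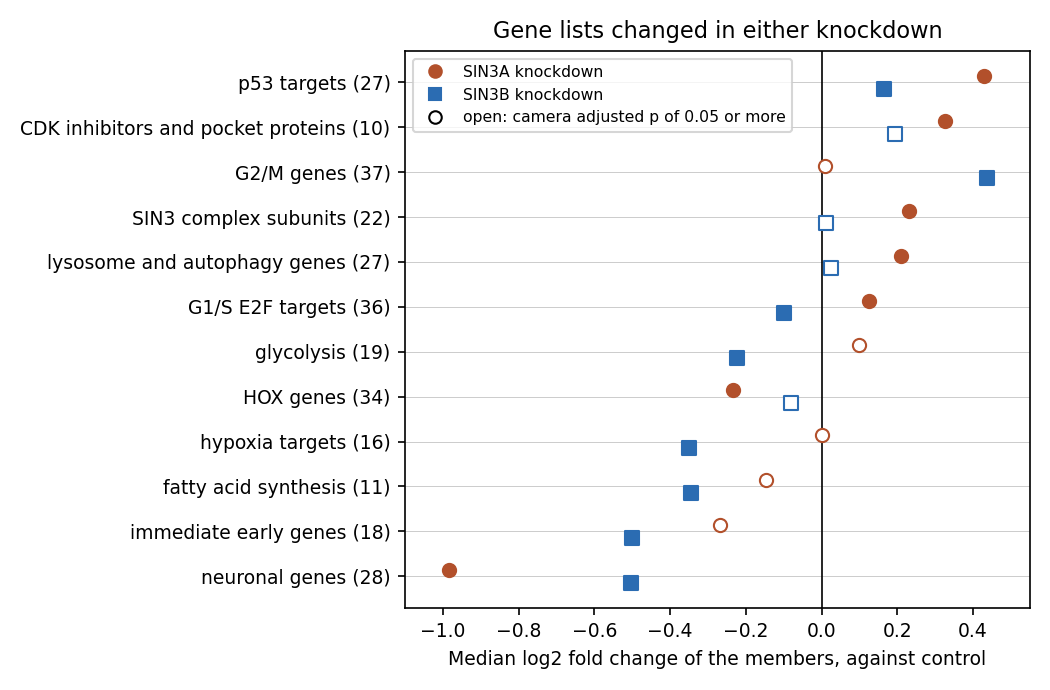
Median log2 fold change against control of the members of each gene list called in at least 1 knockdown, with members tested in parentheses, circles for the SIN3A and squares for the SIN3B knockdown, filled where the camera adjusted p was under 0.05. Neuronal genes lay at -0.985 and -0.503, and G2/M genes at 0.00948 in the SIN3A knockdown and 0.436 in the SIN3B knockdown.

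The third comparison set the 2 knockdowns directly against each other. Cell cycle genes differed in both phases: G1/S genes were higher and G2/M genes lower in the SIN3A knockdown than in the SIN3B knockdown, and lysosomal, glycolytic and hypoxia-responsive genes were higher, by the camera test at its preset correlation. Of the 10 lists called, 0 were called with an estimated correlation (19 lists with fry). Of 16686 genes tested, 2417 were higher and 2110 lower in the SIN3A knockdown (edgeR quasi-likelihood test), with 267 and 297 of them at least 2-fold apart, and with upper-quartile factors 2157 were higher and 2436 lower. SMIM10L2B (log2 difference 2.47 ± 0.16), ITIH5 (2.20 ± 0.38), SPSB2 (2.08 ± 0.28), NXN, a redox regulator of Wnt signalling (1.90 ± 0.11), SPEF1 (1.88 ± 0.41) and TMEM52 (1.85 ± 0.24) were the 6 furthest above. UBE2E3, a ubiquitin-conjugating enzyme (-2.09 ± 0.10), ACSL6 (-2.08 ± 0.35), the cathepsin CTSO (-1.99 ± 0.41), the late endosomal GTPase RAB7A (-1.98 ± 0.06), FAM198A (-1.85 ± 0.33) and HLF (-1.75 ± 0.30) were the 6 furthest below. RAB7A, at 83.0 ± 0.89 CPM in the SIN3A and 327 ± 7.8 CPM in the SIN3B knockdown, held 1 copy of the sequence linked to falls in the SIN3A knockdown, as did ACSL6 and HLF. Of the 6 furthest above, ITIH5 held 2 copies of the sequence linked to falls in the SIN3B knockdown, and NXN and SMIM10L2B 1 each.

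Of 36 G1/S genes, 15 were higher and 1 lower in the SIN3A knockdown (17 and 2 adjusted over the list alone, camera adjusted p = 1.01e-06, adjusted p = 0.26 with an estimated correlation), led by CCNE1 (1.83 ± 0.09), RRM2 (1.15 ± 0.07) and E2F1 (1.08 ± 0.07). Of 37 G2/M genes, 1 was higher and 25 lower (1 and 30 adjusted over the list alone, camera adjusted p = 2.81e-10, adjusted p = 0.26 with an estimated correlation), with PLK1 the higher one (1.27 ± 0.07), and CDCA8 (-0.73 ± 0.07) and KIF20A (-0.69 ± 0.08), which act in cell division, among the lower. Of 13 histone genes, 6 were lower and 0 higher (7 and 0 adjusted over the list alone, camera adjusted p = 0.00116, adjusted p = 0.26 with an estimated correlation), among them HIST2H2BE (-1.60 ± 0.29), HIST1H1C (-1.11 ± 0.17) and H1F0 (-0.39 ± 0.06). Many of these genes make transcripts without a poly-A tail, so a poly-A library holds only part of them.

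Glycolysis genes were higher in 10 and lower in 0 of 19 (11 and 0 adjusted over the list alone, camera adjusted p = 2.05e-05, adjusted p = 0.449 with an estimated correlation), with SLC2A1 at 1.50 ± 0.10, HK1 at 0.54 ± 0.07 and GAPDH at 0.47 ± 0.08. Hypoxia targets were higher in 8 and lower in 0 of 16 (the same counts adjusted over the list alone, camera adjusted p = 0.00514, adjusted p = 0.572 with an estimated correlation), with the vasodilator peptide ADM at 1.23 ± 0.15, PDK1 at 0.68 ± 0.09 and PFKFB3 at 0.55 ± 0.09. Lysosome and autophagy genes were higher in 13 and lower in 2 of 27 (the same counts adjusted over the list alone, camera adjusted p = 0.000186, adjusted p = 0.307 with an estimated correlation), with the lysosomal channel MCOLN1 at 1.02 ± 0.11 and CTSA, which held 1 copy of the sequence linked to falls in the SIN3B knockdown, at 0.97 ± 0.08. HOX genes were higher in 3 and lower in 13 of 34 (3 and 15 adjusted over the list alone, camera adjusted p = 0.0251, adjusted p = 0.307 with an estimated correlation), with HOXA13 higher (0.86 ± 0.12) and HOXA7 (-0.82 ± 0.11) and HOXA10 (-0.53 ± 0.07) lower.

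Of 27 p53 targets, 7 were higher and 3 lower in the SIN3A knockdown (the same counts adjusted over the list alone), with CDKN1A at 1.53 ± 0.09, BTG2 at 0.87 ± 0.09 and BAX at 0.71 ± 0.08. Their camera adjusted p was 0.0293, and the adjusted p was 0.26 with an estimated correlation. Of 17 DNA-binding and other SIN3 partners, 7 were higher and 2 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.0263, adjusted p = 0.572 with an estimated correlation), with MXI1 at 1.16 ± 0.10, MAX at 0.56 ± 0.08 and MXD4 at 0.50 ± 0.08. Of 18 immediate early genes, 6 were higher and 1 lower (the same counts adjusted over the list alone, camera adjusted p = 0.0263, adjusted p = 0.449 with an estimated correlation), with SRF at 0.65 ± 0.08 and MYC at 0.42 ± 0.07. Each of these 3 calls was lost without 1 library: without SIN3A knockdown replicate 3 the camera adjusted p was 0.0934 for p53 targets and 0.103 for SIN3 partners, and without SIN3A knockdown replicate 2 it was 0.0547 for immediate early genes. They were also lost with counts divided by 4 (0.0592, 0.0524 and 0.0524) and without genes with a seed-type site in the 3 prime UTR (0.373, 0.396 and 0.0579), for p53 targets, SIN3 partners and immediate early genes in turn. Without genes with a seed-type site anywhere in the mRNA the camera adjusted p was 0.568 for p53 targets and 0.922 for SIN3 partners, whose median was then 0.000801 against 0.239, and with offsets for GC content and exon length it was 0.08 for immediate early genes. The sequence linked to falls in the SIN3B knockdown stood in CDKN1A, BTG2, MXI1 and MXD4 (1 copy each) and SRF (2 copies).

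The fourth comparison asked how far the 2 knockdowns changed the same genes. Of 1522 genes called in both, 743 rose in both, 513 fell in both, and 266 went in opposite directions. Independent lists of these sizes would share 243.3 rises and 209.9 falls. Simulated unchanged groups set against the same controls shared 0.05 calls on average. Only 0.2 (SIN3A) and 0.3 (SIN3B) genes were called there, so this level cannot show how shared controls raise the overlap of long lists. Among genes that rose in both, the fixed rule names EIF5A2 and ZNF547, and it also names CCDC168, B3GNT7 and PLEKHS1 from fits against control libraries at 0. These 3 had no count in the control libraries and 0.260 to 0.512 CPM in the knockdowns, near the floor, so no fold is given, and ZNF547 went from 0.688 ± 0.54 to 2.07 ± 0.79 (SIN3A knockdown) and 1.89 ± 0.58 CPM (SIN3B knockdown), calls that were lost in 6 of 19 and 11 of 18 alternatives. The 5 largest common falls were those of the membrane metalloproteinase MMP24, the interleukin-12 receptor subunit IL12RB2, STUM, C1orf61 and FAM43B, all under 12 CPM in control libraries. All 5 held the sequence linked to falls in the SIN3B knockdown in the 3′ UTR (2 copies in MMP24 and STUM, 1 in the others). Of the genes searched, all above 2 log2 CPM and so not matched to these 5 in expression, 25.9% held it. STUM fell by 1.79 ± 0.21 in the SIN3A knockdown and 1.67 ± 0.21 in the SIN3B knockdown.

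Of the 266 opposite genes, 194 rose in the SIN3A and fell in the SIN3B knockdown, and 72 did the reverse, where independent lists would give 235.7 and 216.7. All 266 also differed in the direct comparison, which all but follows from 2 opposite calls against the same controls and adds no evidence. CCNE1 rose by 1.01 ± 0.08 and fell by 0.82 ± 0.09, SERTAD3, a transcriptional coregulator, rose by 0.84 ± 0.11 and fell by 0.83 ± 0.12, TMEM52 rose by 1.03 ± 0.23 and fell by 0.82 ± 0.25, and SMIM10L2B, with 1 copy of the SIN3B-linked sequence, rose by 1.32 ± 0.15 and fell by 1.15 ± 0.16. HLF, a circadian-regulated bZIP factor, fell by 0.93 ± 0.31 with SIN3A knockdown and rose by 0.83 ± 0.29 with SIN3B knockdown, but its fall was lost in 8 and its rise in 13 of 19 alternatives. CDKN1A, named above, was another opposite gene. Across the 16686 genes the Pearson correlation of the log2 fold changes was 0.435, below the 0.508 of simulated unchanged groups that share the controls, and 63.1% of genes had the same sign against 66.9% in the simulation. Changes found in only 1 knockdown lower both of these measures, so they cannot tell how alike the knockdowns were. The covariance was 0.140 against 0.0567, above the level that shared controls alone gave in the simulation. Over the 11645 genes of at least 2 log2 CPM the correlation was 0.385 against 0.504 and the covariance 0.0487 against 0.00939. Genes are not independent replicates, and with 3 control libraries, too few to give each knockdown its own, part of the excess in common calls may come from the shared controls.

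The numbers of common and opposite calls changed when single libraries were left out. Several named genes lost a call with 1 library fewer while their fold changes stayed close. Without control replicate 1, for example, the SIN3A knockdown gave -2.121 for IL12RB2 (edgeR adjusted p = 0.0515), -2.150 for MMP24 (edgeR adjusted p = 0.12), 1.506 for ZNF547 (edgeR adjusted p = 0.0975) and -0.860 for HLF (edgeR adjusted p = 0.101), and the SIN3B knockdown -0.755 for TMEM52 (edgeR adjusted p = 0.0734). B3GNT7 (0.0545) and PLEKHS1 (0.0732) also missed the threshold there. In the SIN3B knockdown the call was lost in 7 of 14 alternatives for MMP24, 4 of 15 for IL12RB2 and 7 of 19 for TMEM52, and in the SIN3A knockdown in 4 of 14 for MMP24 and 2 of 16 for IL12RB2. The common calls numbered 790 without control replicate 2 and 760 without control replicate 3. The opposite calls numbered 124, 117 and 136 without control replicates 1, 2 and 3, 409 without SIN3A knockdown replicate 1, and 164 and 172 without SIN3B knockdown replicates 2 and 3.

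**Figure D3:**
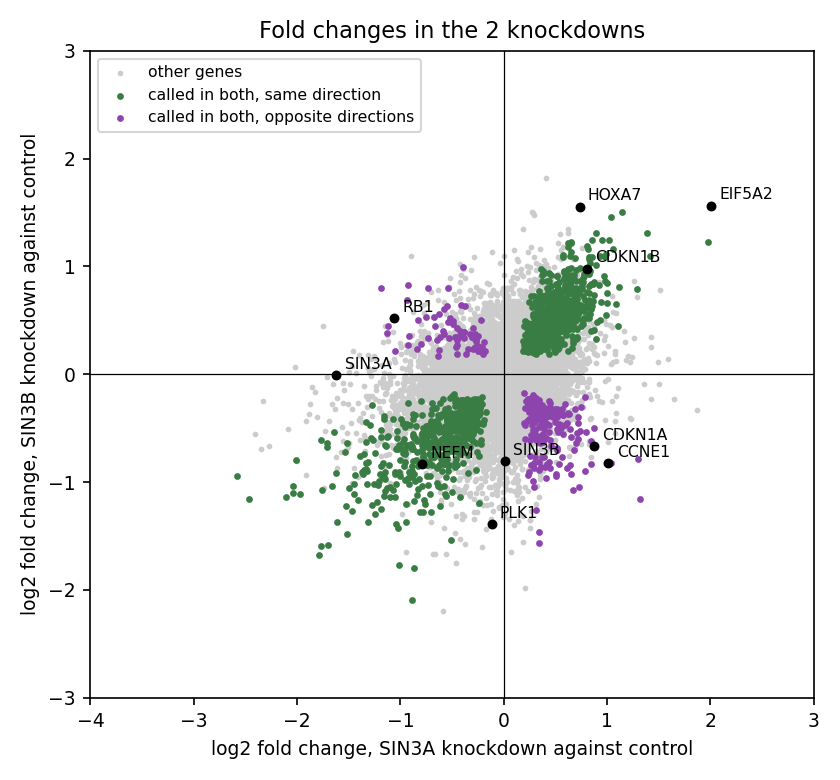
Log2 fold change of each gene of at least 1 log2 CPM in the SIN3A knockdown (horizontal axis) and the SIN3B knockdown (vertical axis), both against the same control libraries, with green points for the 1236 drawn genes called in both in the same direction, purple for the 266 called in opposite directions, and black for genes named on the plot. EIF5A2 stands at 2.01 and 1.56, CCNE1 at 1.01 and -0.82, and SIN3A at -1.62 and -0.01.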

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

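Counts divided by 4, GC and length offsets, lists under upper-quartile factors, and leaving out genes with a seed-type site were chosen after seeing the data. Against a fold change of 1.2, 1208, 1397 and 1902 genes were called (SIN3A, SIN3B, direct comparison) in place of 3836, 3939 and 4527. Without genes with a site anywhere in the mRNA, 1846 (SIN3B) and 1769 (direct) were called, and without those with a 3′ UTR site 2977 (direct) and 141 opposite genes, in part because fewer genes were tested. Lists called numbered 7, 8 and 10, but 2, 0 and 0 with an estimated correlation and 13, 17 and 19 with fry. Without 1 library, SIN3A lists ranged from 7 to 11 (the latter without SIN3A knockdown replicate 1, with cytosolic ribosomal proteins, SIN3 partners, histones and ATF4 targets added). The uncalled log2 fold change of SIN3B in the SIN3A knockdown changed sign to -0.059 (upper-quartile factors), -0.002 (FPKM length offsets, whose lengths do not match the annotation) and -0.003 (counts divided by 4), and ranged from -0.056 to 0.115 without 1 library. That of SIN3A in the SIN3B knockdown went to 0.004 (stricter filter), 0.017 (GC and length offsets) and 0.018 (these with the replicate block), and ranged from -0.033 to 0.012. Other uncalled values that changed sign were those of FOXK1 in the SIN3B knockdown, at 0.084 with GC and length offsets and 0.086 with these and the replicate block, and HDAC2 there, at -0.189 and -0.191. Without 1 library, for FOXK1, SIN3A knockdown against control gave -0.268 to 0.131, for FOXK1, SIN3B knockdown against control gave -0.146 to 0.008, and for MXD1, SIN3B knockdown against control gave -0.144 to 0.053. Of 3086 values of 165 named results, 2978 kept direction and side of the threshold, 93 lost the call, 7 gained it and 8 changed sign. The correlation ranged from 0.337 (without SIN3A knockdown replicate 3) to 0.574 (without control replicate 2). Common calls ranged from 760 to 1406 and opposite calls from 117 to 409, with 124, 117 and 136 without control replicates 1, 2 and 3, 409 without SIN3A knockdown replicate 1, and 164 and 172 without SIN3B knockdown replicates 2 and 3. Common calls were 790 and 760 without control replicates 2 and 3. With the replicate block 3478, 3654 and 4239 genes were called. The labels do not say whether a replicate number pairs libraries across groups. After removal of group means, libraries of different groups correlated at -0.0265 to 0.036 with the same number and -0.0487 to 0.0357 with other numbers. The cause of the moves between settings was not tested.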

Other observations

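The tests of 7-base sequences were chosen after a scan of the same data had named the sequences, and the readings of the G2/M and neuronal lists after those lists had been called; how the site count in PLK1 was read was settled after its value was seen, and the counts over other splits of the libraries were planned. The siRNA sequences are not given, so none was at hand to compare with these sequences.

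Among list genes outside the called lists, the heme oxygenase HMOX1 fell in both knockdowns, by 1.44 ± 0.14 with SIN3A siRNA and 0.93 ± 0.14 with SIN3B siRNA, and held 1 copy of the 7-base sequence linked to falls in the SIN3A knockdown. The adhesion protein CDH1 (-1.55 ± 0.19) and the Wnt target LGR5 (-1.40 ± 0.23) fell in the SIN3A knockdown. In the SIN3B knockdown the endoplasmic reticulum factor MANF, with 1 copy of the sequence linked to falls there, fell by 1.36 ± 0.08 and the cystine transporter SLC7A11 rose by 1.14 ± 0.19. Of 13 genes of the RNA interference machinery, 5 rose and 2 fell there (the same counts adjusted over the list alone, camera adjusted p = 0.0919), among them DICER1 (0.63 ± 0.10), TNRC6A (0.44 ± 0.07) and TNRC6B (0.59 ± 0.08).

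In the SIN3A knockdown, genes with GGTCTAA or AGGTCTA in the 3′ UTR tended to fall (t of the first -11.06, and -0.92 in the SIN3B knockdown), and in the SIN3B knockdown those with ACAGCCT or CAGCCTT (t -18.84, and 0.14 in the SIN3A knockdown). Other arrangements of the same 7 bases reached a t of -3.57 and -5.74, which argues against base composition of the 3′ UTR as the whole cause. A weaker composition trend is present, since -5.74 lies beyond the 4.75 of permuted values and AT-rich sequences went with rises in both knockdowns (AATTATA, t 5.68 and 6.89). Genes with 2 or more copies had lower medians than genes with 1, by a difference of -0.143 (one-sided permutation p = 0.0031) in the SIN3A and -0.05 (one-sided permutation p = 0.0017) in the SIN3B knockdown. Unlike the scan, this comparison was not adjusted for 3′ UTR length, GC content or expression, which may differ with the number of copies. These values are consistent with seed-type action of each siRNA on mRNAs other than its target, a hypothesis that needs the siRNA sequences or a further siRNA per target. Loss of SIN3A or SIN3B stays open for the genes without such a sequence, and for those with one it was not tested apart.

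Of 37 G2/M genes, 28 rose in the SIN3B knockdown, 8 were not called and PLK1 fell, and the list call was lost with an estimated correlation (adjusted p = 0.079, camera). With offsets for GC content and exon length the median of the 37 genes was 0.399, against 0.436 without, which argues against these trends as the whole cause. The PLK1 3′ UTR held 1 copy of the sequence linked to falls in that knockdown, so seed-type action of the SIN3B siRNA on PLK1 mRNA may contribute to its fall. The whole PLK1 transcript held 2 copies. That evidence is weak, since 25.9% of searched genes held such a sequence, and it bears on PLK1, not on the rise of the other genes. Of searched genes that fell at least 2-fold in that knockdown, 63 of 106 (59.4%) held one, in the same data that named the sequence. The fitted log2 shift that went with ACAGCCT was -0.178, far smaller than the fall of PLK1. A change in the share of cells in G2 or M, whether through loss of SIN3B or of PLK1, stays open and was not measured.

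Of 28 neuronal genes, 14 fell in the SIN3A and 9 in the SIN3B knockdown, and the list call in the latter was lost with an estimated correlation (adjusted p = 0.079, camera). The 21 of 28 members with neither sequence in the 3′ UTR had medians of -0.998 (SIN3A) and -0.404 (SIN3B). These values argue against those 3′ UTR sequences as the whole cause. Copies in coding sequence (t -5.36 for SIN3A, -11.31 for SIN3B) and related sequences such as TGGTCTA (t -9.09, SIN3A) and CAGCCTA (t -11.95, SIN3B) also went with falls. The 21 members were not screened for either kind. A separate setting left out genes with a seed-type site anywhere in the mRNA, coding copies included. There the camera call at the preset correlation held in both knockdowns. Related sequences were screened in no setting, so seed-type action through them stays open. Low expression of the members was set against 10000 random lists of like expression, and the list median lay at percentile 0 in both knockdowns. With offsets for GC content and exon length 91.9% and 79.7% of the median was kept. Over 13 alternative settings the list median ranged from -1.08 to -0.905 in the SIN3A and from -0.757 to -0.244 in the SIN3B knockdown. An effect of either SIN3 protein on these genes may underlie the pattern, as a hypothesis found and tested on the same libraries, and the shared control libraries stay open as a source of part of the likeness.

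Of the 10 splits of 6 libraries into 3 and 3, only 1, the real one, gave as many calls in each comparison. The real splits called 3151 (SIN3A against control), 5358 (SIN3B against control) and 3897 genes (SIN3A against SIN3B knockdown) in edgeR fits of 6 libraries, and the highest of the other splits called 0. With 10 splits the share cannot fall under 0.05. Every other split put libraries of both groups on each side, so group differences widened its spread and few calls were to be expected. The counts of 0 are therefore no separate evidence for the real split.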
